A study of Arabidopsis thaliana with 12 samples.

How the data were processed

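RNA polymerase II occupancy was measured by chromatin immunoprecipitation and sequencing in Arabidopsis thaliana seedlings of the Columbia ecotype, 10 days after sowing, with antibodies against the serine 2 phosphorylated (S2P) or serine 5 phosphorylated (S5P) C-terminal domain of the polymerase. Per the labels' protocols, plants grew at 22 °C with 16 h of light and 8 h of dark, and were exposed for 24 h to 2 mM β-estradiol or to ethanol as mock. Material of 1 g was crosslinked with 1% formaldehyde, and libraries were made with a SMART ChIP-seq kit. The plants carried an insertion in TFIIS (AT2G38560), a transcript elongation factor, and an estradiol-inducible GFP fusion of it. The labels name GFP-TFIIS for the induced S2P libraries and GFP-TFIISmut, a mutated form, for the induced S5P libraries, while the series title speaks of the mutated form, so antibody and induced protein cannot be told apart. No wild-type plants, input chromatin or mock immunoprecipitation were used here. All induced libraries came from plants given estradiol and all mock libraries from plants given ethanol. A response to estradiol thus cannot be told apart from a response to the induced protein.

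The authors deposited 36 files of raw read counts per gene, 1 for each of 3 windows (whole gene, TSS and gene body) in each of 12 libraries. Per the submitters' processing notes the tools were Trimmomatic and HTSeq and the genome build was TAIR10; no versions are given. The aligner and the bounds of the windows are not given in the sources used here. The deposited counts are whole numbers with no normalization. Each file ends with 5 lines of the counter that name no gene, which were left out of library sizes and tests. Over the libraries these lines show 74.7% to 96.7% of reads not aligned. Reads outside annotated genes were 16.1% to 38.6% of counted alignments. The line for alignments that are not unique was 0 in every library, so reads shared by near-identical genes are not visible. Strand use is not stated, so overlapping and antisense genes may share reads.

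The whole gene files hold 33323 nuclear genes, and the TSS and gene body files 29899. The 279 organelle genes were left out of the tests. Symbols were taken from a RefSeq gene table of assembly TAIR10.1, which matched 32835 nuclear genes; no coordinates were taken from it. Whole gene counts ranged from 115868 to 2537034 per library, and 4 of the 12 libraries had fewer than 250000. Sequencing reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only.

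Groups came from the labels: S2P mock, S2P induced, S5P mock and S5P induced, with 3 replicates each. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Names of the files of induced replicate 3 carry another number; the number in the labels was kept. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors, filterByExpr with a minimum count of 10 and a Benjamini-Hochberg adjusted p threshold of 0.05, fitted per antibody on 6 libraries. The balance of TSS and gene body counts of each gene was tested as a window-by-induction term with the library as a block. Each window was scaled on its own there, which removes a shift shared by all genes. The balance summed over genes was compared by an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p below 0.1. A comparison of S5P with S2P used the 6 mock libraries, and an interaction term used all 12. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. In mock plants, libraries with the same replicate number deviated together between the antibodies, with correlations of deviations from the group means of 0.223, 0.309 and 0.495 over 15050 genes, so the numbers pair the mock libraries there and a fit with the replicate number as a block is given beside the result. Numbers did not pair mock with induced libraries.

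Before the data were examined, 19 gene lists with 451 genes were written down: photosynthesis, cytosolic ribosomal proteins, heat shock and chaperones, xenobiotic detoxification, proteasome, polymerase II elongation machinery, DNA damage, salicylate and defence, jasmonate, auxin response, ethanol and hypoxia, touch, cold and elicitor early response, circadian clock, histones, mitotic cell cycle, flavonoids, glucosinolates, root markers, and silent reproductive and seed genes. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, with camera with an estimated correlation, and with fry. A list needed 5 tested genes.

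Genes were named by a rule fixed at the same time: TFIIS always; for each antibody, genes past the threshold whose groups do not overlap, up to 12 per direction for the whole gene and 4 for the other tests; where fewer than 5 pass in a direction, the 5 with the smallest p, said not to pass; and up to 4 members of each list with the smallest p. Genes named for other reasons are said to have been chosen after their values were seen.

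Alternatives fixed before the data were examined were RLE factors, total counts, upper quartile factors, DESeq2 1.42.0, limma voom, voom with cyclic loess, no count filter, a minimum count of 30, organelle genes kept in, the replicate block and each library left out in turn. Added after the data had been seen were a fit of induction over both antibodies, counts summed over the antibodies, only the 8 libraries with at least 250000 counts, regroupings that keep same-numbered libraries together, and the share of reads outside genes as a covariate. The covariate was added because that share followed the TSS balance within groups, and of all settings with every library in the fit it calls the most genes in each whole gene test of induction; it is never the main result.

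Each edgeR test was tested on simulated counts with 200 changed genes, and camera on simulated counts with 1 list raised. With 3 against 3 libraries of S2P, 5.97% of genes changed 2-fold, 55.2% of those changed 4-fold and 95.5% of those changed 8-fold were recovered over 18871 genes. For S5P the shares were 4.48%, 55.2% and 93.9% over 21637 genes, so 2-fold changes were mostly not detectable at this depth and spread. The simulated counts gave every gene the same spread between libraries, and no structure shared by genes within a library. Recovery in the real data may therefore be lower than these shares. In the TSS window, 53.0% of genes changed 8-fold were recovered for S2P over 3496 genes and 60.6% for S5P over 5948 genes. Python 3.11.15 with SciPy 1.17.1 was used for loading and figures.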

Results

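Occupancy of S2P and S5P RNA polymerase II was profiled in 12 libraries from 10-day-old seedlings, with 3 mock and 3 estradiol-induced libraries for each antibody. S2P is the phosphorylation carried mostly by elongating polymerase in the gene body, and S5P the one carried mostly by polymerase near the transcription start site (TSS). The S2P mock libraries held 159951, 192044 and 2537034 reads in nuclear genes, and the S2P induced libraries 1650892, 1156568 and 210421. For S5P the mock libraries held 628487, 362807 and 1277600 reads, and the induced libraries 1648866, 115868 and 1341826. The deepest library thus had 21.9 times the reads of the shallowest. Values per library are given as CPM, the reads of a gene scaled to a common total of reads in nuclear genes.

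TFIIS (AT2G38560), the gene carried by the inducible transgene, was examined first, as a check on the labels of induction. Its whole gene S2P occupancy was 48.1 ± 25.9 CPM in mock and 93.7 ± 31.8 CPM in induced plants (SD, n = 3). For S5P the levels were 51.2 ± 6.69 and 126 ± 72.8 CPM (SD, n = 3). The log2 fold changes were 1.09 (SE 0.42) for S2P and 1.52 (SE 0.49) for S5P, neither past the threshold in edgeR (adjusted p = 0.573 and 0.580). In the gene body the levels were 48.0 ± 22.2 in mock and 103 ± 25.9 CPM in induced plants for S2P, and 48.7 ± 5.99 and 142 ± 69.5 CPM for S5P (SD, n = 3). In the TSS window they differed by less than the spread between libraries, with 43.5 ± 37.7 and 54.9 ± 41.2 CPM for S2P and 60.2 ± 4.71 and 64.6 ± 64.6 CPM for S5P (SD, n = 3). Over the whole gene, S5P induced replicate 2 had 43.2 CPM from 5 counts, below every S5P mock library. S2P induced replicate 3 had 61.8 CPM from 13 counts, below S2P mock replicate 2 at 67.7 CPM. In the gene body these 2 libraries had 62.3 CPM from 5 counts and 75.4 CPM from 12 counts, above every mock library of their antibody. Without S5P induced replicate 2, the whole gene S5P log2 fold change was 1.82 and edgeR's adjusted p was 0.00721. Over 18 alternative settings that adjusted p ran from 0.00649 to 0.989.

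The study asked how occupancy in induced plants differs from that in uninduced plants, for each antibody. With the S2P antibody, 3 genes rose after induction and none fell. AT2G04070, which encodes a MATE efflux transporter, rose from 20.1 ± 4.71 to 168 ± 7.83 CPM (SD, n = 3). UGT74E2 (AT1G05680), a glucosyltransferase, rose from 19.5 ± 4.92 to 119 ± 36.3 CPM, and SRO3 (AT1G70440), a relative of the stress regulator RCD1, from 15.4 ± 3.47 to 90.5 ± 18.3 CPM (SD, n = 3). Their log2 fold changes were 3.27 (SE 0.44), 2.85 (SE 0.41) and 2.94 (SE 0.43), or 9.61, 7.21 and 7.66 times, each with an adjusted p of 0.0472 in edgeR and no overlap between the groups. In S2P mock 1 and 2, 3 reads equal 18.8 and 15.6 CPM, so the mock levels of these genes rest on few reads there. The 25 silent reproductive and seed genes together held 458 ± 112 CPM in S2P mock libraries (SD, n = 3). Gene length aside, the mock levels of the 3 genes were thus near the mean of silent genes. Without input chromatin, polymerase and background cannot be told apart at that level, so the fold changes are relative to it. AT2G04070 lies in a family of similar transporter genes, so its value is uncertain where copies share reads.

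Among genes that did not pass, those with the smallest p on the higher side included NAC13 (AT1G32870), a transcription factor of mitochondrial stress signalling, with a log2 fold change of 2.86 (SE 0.48). PAD3 (AT3G26830), the last enzyme of camalexin synthesis, had 2.57 (SE 0.44), and the lectin receptor kinase LECRKA4.2 (AT5G01550) 2.46 (SE 0.42), each with an adjusted p of 0.0994 in edgeR. On the lower side, AT2G34510 had -1.71 (SE 0.36), AT2G26215 -1.83 (SE 0.41), AT4G18220 -1.65 (SE 0.37) and the microRNA gene MIR167d (AT1G31173) -2.04 (SE 0.47), with adjusted p from 0.17 to 0.20. Of 18798 genes tested, 1438 had an unadjusted p under 0.05. DESeq2 called 42 genes and limma voom 1. The count of 3 rests on every library but S2P induced 2 and 3: it was 0 without any mock library or without S2P induced 1, 40 without S2P induced 3 and 526 without S2P induced 2. It was also 0 with RLE factors, with upper quartile factors, with cyclic loess and with organelle genes kept in.

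**Figure D1:**
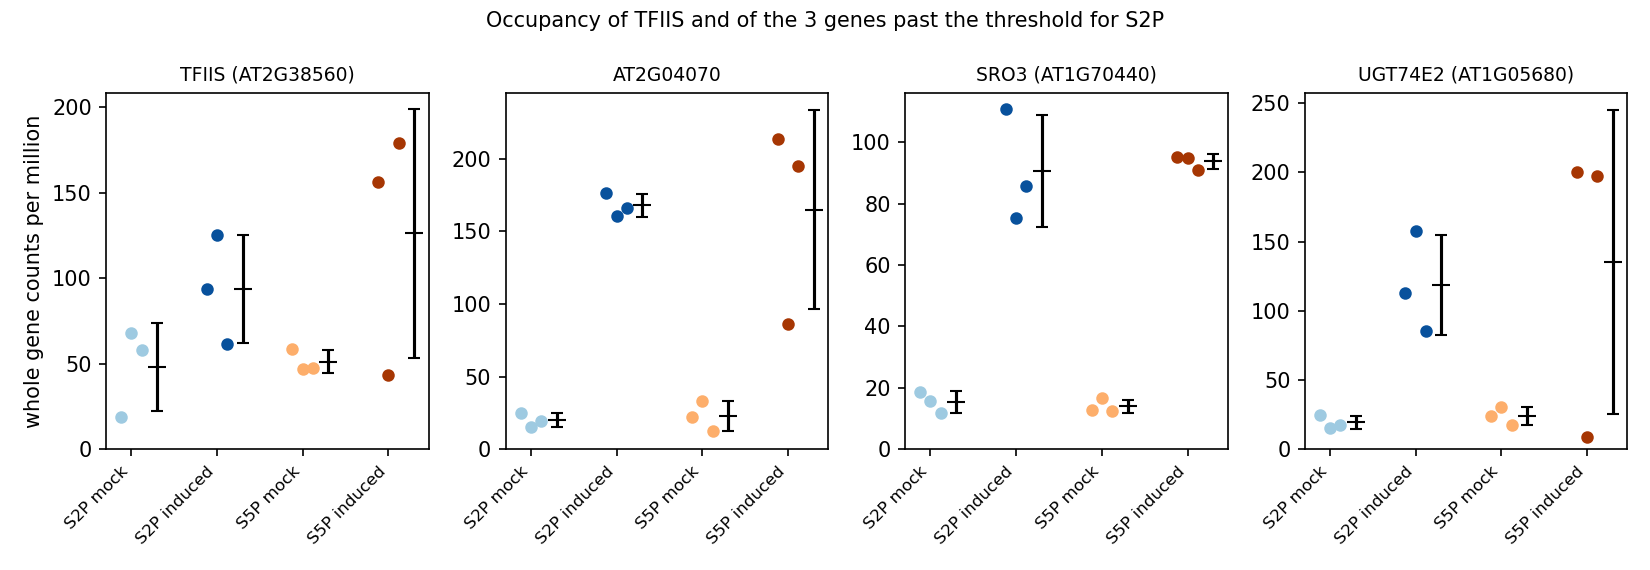
Whole gene CPM of TFIIS and of the 3 genes past the threshold for S2P, for each of the 12 libraries. Coloured points are libraries and black bars are group means with SD (n = 3). AT2G04070 lies between 161 and 176 CPM in the S2P induced libraries and between 15.6 and 25.0 CPM in the S2P mock libraries.

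Genes of xenobiotic detoxification, which encode enzymes and transporters that conjugate and export foreign compounds, were higher as a list for S2P with camera's preset correlation (adjusted p = 6.11e-11), a call lost with an estimated correlation (adjusted p = 0.236). Whether they answered to the estradiol itself or to the induced protein cannot be told apart. Of 24 tested members 22 had a positive fold change, with a median log2 fold change of 1.22; 2 passed over all genes and 12 passed adjusted over the list alone. Among them were AT2G04050, a further MATE transporter gene, with 2.55 (SE 0.51), the cytochrome P450 gene CYP81D8 (AT4G37370) with 2.33 (SE 0.47) and the glutathione transferase gene GSTF7 (AT1G02920) with 1.80 (SE 0.42). The proteasome list was called higher by camera too and lost with an estimated correlation (adjusted p = 0.236). Its median was 0.60 with 45 of 46 positive; 0 members passed over all genes or adjusted over the list alone in edgeR, and 13 had an unadjusted p under 0.05. PBD1 (AT3G22630) and PAE2 (AT3G14290), subunits of the core particle, had 1.31 (SE 0.37) and 1.51 (SE 0.43). Salicylate and defence genes, called higher by camera and not with an estimated correlation (adjusted p = 0.113), had a median of 0.67, with 15 of 15 positive and 4 past the threshold adjusted over the list alone. Among members, EDS1 (AT3G48090), a hub of defence signalling, had 1.44 (SE 0.40) and WRKY70 (AT3G56400) 1.90 (SE 0.55).

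Camera's preset correlation also called the polymerase II elongation machinery for S2P, with a median of 0.34 and 16 of 17 positive, heat shock and chaperones, with 0.35 and 12 of 16, and DNA damage genes, with 0.77 and 8 of 10. These calls were lost with an estimated correlation (adjusted p = 0.236, 0.236 and 0.241), and with total counts the first 2 medians were 0.16 and 0.14. Members of these lists included VIP5 (AT1G61040) with 0.86 (SE 0.34), HSP70 (AT3G12580) with 1.19 (SE 0.35) and NAC044 (AT3G01600) with 1.23 (SE 0.42). The adjusted p of the 6 lists with camera's preset correlation ran from 6.11e-11 for detoxification to 0.0198 for DNA damage. fry called salicylate and defence and the elongation machinery.

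Photosynthesis genes had a median of -0.37 for S2P, with 11 of 45 positive, and did not pass (camera adjusted p = 0.0585). Medians of the other lists that did not pass were -0.35 for jasmonate, -0.23 for root markers, -0.08 for touch, cold and elicitor early response, 0.60 for auxin response, 0.39 for glucosinolates, -0.18 for mitotic cell cycle, 0.04 for silent reproductive and seed genes, -0.16 for flavonoids, -0.03 for histones, 0.08 for cytosolic ribosomal proteins, -0.02 for circadian clock and -0.07 for ethanol and hypoxia. With other scalings the signs of the touch and cold, silent, histone, ribosomal and clock medians turned, and camera's direction was opposite to the median for touch and cold, histones, clock, ribosomal proteins and silent genes.

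With the S5P antibody, no gene passed the threshold. The genes with the smallest p on the higher side included AT3G58150, at 4.87 ± 1.88 CPM in mock and 53.9 ± 33.2 CPM in induced plants, and SRO3, at 13.9 ± 2.26 and 93.7 ± 2.40 CPM (SD, n = 3). Their log2 fold changes were 3.67 (SE 0.48) and 2.95 (SE 0.40). In the S5P mock libraries 3 reads equal 4.77, 8.27 and 2.35 CPM, so the mock level of AT3G58150 rests on few reads. WRKY51 (AT5G64810), a transcription factor gene, had 2.47 (SE 0.37) and the glutathione transferase gene GSTU9 (AT5G62480) 2.68 (SE 0.40). Each of these 4 had an adjusted p of 0.0853 in edgeR. On the lower side, PROPEP1 (AT5G64900), the precursor of a danger peptide, had -2.16 (SE 0.46), ORA47 (AT1G74930), a jasmonate-related transcription factor, -2.55 (SE 0.54) and AT4G32340 -2.03 (SE 0.46), with adjusted p from 0.25 to 0.31.

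The S5P count was 0 of 21954 genes in edgeR, where 1648 had an unadjusted p under 0.05; DESeq2 called 92 genes and limma voom 0. Without S5P induced replicate 2, the shallowest library, 302 genes passed, 288 higher and 14 lower.

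**Figure D2:**
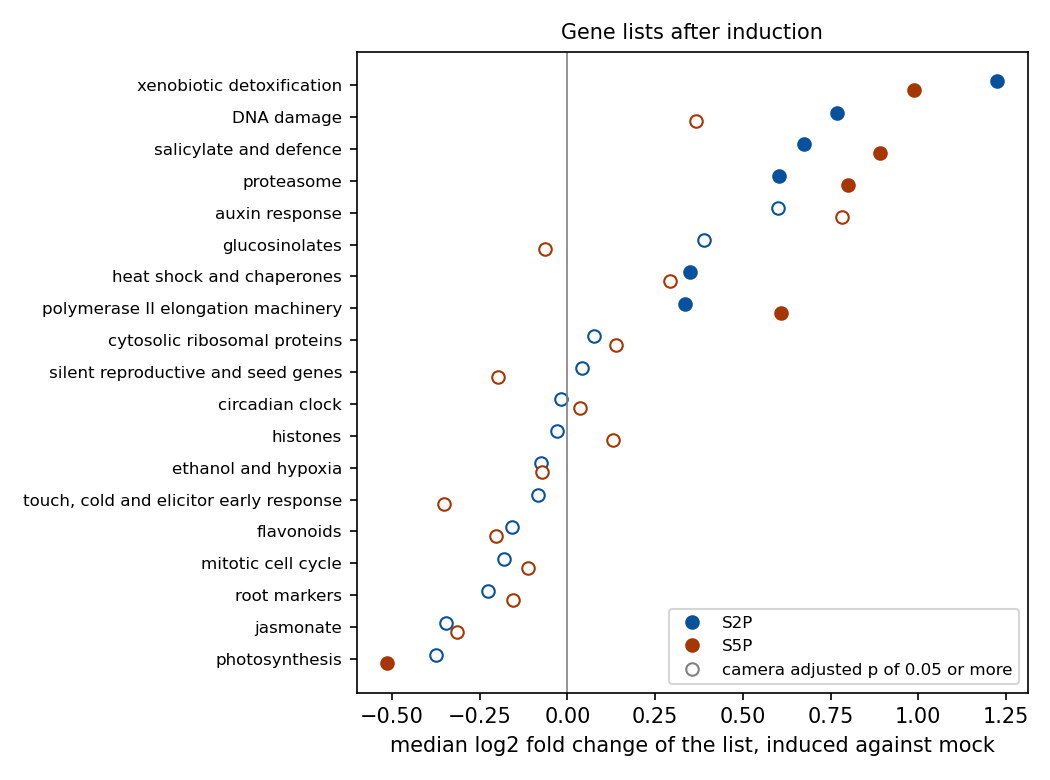
Median log2 fold change, induced against mock, of each gene list fixed before the data were examined, for S2P in blue and S5P in orange. Filled points passed camera with a preset correlation, and none of them passed with an estimated correlation; xenobiotic detoxification lies highest for S2P, at 1.22.

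For S5P, camera's preset correlation called detoxification, proteasome, salicylate and defence, and elongation machinery genes higher and photosynthesis genes lower. None of the 5 calls held with an estimated correlation (adjusted p = 0.525, 0.525, 0.161, 0.604 and 0.894), and fry called 0 lists. Detoxification had a median of 0.99 with 23 of 25 positive and 9 past the threshold adjusted over the list alone, against 0 over all genes in edgeR; GSTU24 (AT1G17170) had 1.83 (SE 0.35). Proteasome genes had a median of 0.80 with 44 of 46 positive and 0 past the threshold adjusted over the list alone, and occupancy of PBD2 (AT4G14800) and PAD1 (AT3G51260) was 2.15 times that in mock plants for both (SE of log2 0.36 and 0.37). Salicylate and defence genes had 0.89 with 15 of 16 positive; WRKY70 had 2.80 (SE 0.67) and PBS3 (AT5G13320), which makes a salicylate precursor, 1.56 (SE 0.40). The elongation machinery had 0.61 with 15 of 18 positive and 0 past the threshold adjusted over the list alone; over 7 scalings its median ran from 0.026 to 0.61, the lowest with cyclic loess. Photosynthesis genes had a median of -0.51 with 6 of 49 positive and 0 past the threshold adjusted over the list alone; RBCS1B (AT5G38430), a Rubisco small subunit, had -1.63 (SE 0.40) and the carbonic anhydrase gene CA1 (AT3G01500) -0.83 (SE 0.34). Camera's adjusted p ran from 5.61e-09 to 0.0376 with the preset correlation.

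Medians of the S5P lists that did not pass were 0.29 for heat shock and chaperones, 0.37 for DNA damage, 0.78 for auxin response, -0.31 for jasmonate, -0.35 for touch, cold and elicitor early response, -0.11 for mitotic cell cycle, 0.13 for histones, -0.20 for silent reproductive and seed genes, -0.16 for root markers, 0.14 for cytosolic ribosomal proteins, 0.04 for circadian clock, -0.20 for flavonoids, -0.06 for glucosinolates and -0.07 for ethanol and hypoxia. With other scalings the signs of the histone, silent, root, ribosomal, clock, flavonoid, glucosinolate and hypoxia medians turned, and camera's direction was opposite to the median for touch and cold and for ethanol and hypoxia. Within these, the clock genes LHY (AT1G01060) and PRR9 (AT2G46790) had 0.90 (SE 0.34) and 1.68 (SE 0.35), and AT5G51440, a small heat shock protein gene, 2.15 (SE 0.44).

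Occupancy in the TSS window and in the gene body was compared to ask whether polymerase shifted along genes. AT2G04070 rose in the gene body for S2P, to 9.86 times the mock level (SE of log2 0.44, adjusted p = 0.0409 in edgeR), and in the TSS window had a log2 fold change of 2.16 (SE 0.84), not past the threshold. For S2P 1 of 15968 genes passed in the gene body and 0 of 3215 in the TSS window, with 1220 and 116 at an unadjusted p under 0.05; DESeq2 called 24 and 0 and limma voom 1 and 0. For S5P edgeR called 0 of 18722 in the gene body and 0 of 5753 in the TSS window, with 1485 and 250 at an unadjusted p under 0.05, the latter 68 higher and 182 lower; DESeq2 called 52 and 0 and limma voom 0 and 0. The TSS to gene body ratio of single genes gave 0 calls of 2600 for S2P and 0 of 5066 for S5P in edgeR, with 30 and 77 at an unadjusted p under 0.05 and 0 by limma. Of these, 17 were higher and 13 lower for S2P, and 15 higher and 62 lower for S5P.

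Summed over genes, the TSS window held 21.5 ± 1.29% of TSS and gene body reads in S2P mock and 25.5 ± 1.93% in S2P induced libraries (SD, n = 3). For S5P it held 22.8 ± 1.02% and 27.2 ± 5.72% (SD, n = 3). The difference in log2 TSS over gene body was 0.32 for both antibodies. The exact two-sided permutation test gave p = 0.1 for S2P, the smallest it allows, with no overlap between the groups, and p = 0.3 for S5P. Without S5P induced replicate 2 the S5P difference was 0.09. Taken as a median over genes, with 1 count added to each window, the S2P difference was -0.050. The added count pulls shallow libraries toward 0.

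**Figure D3:**
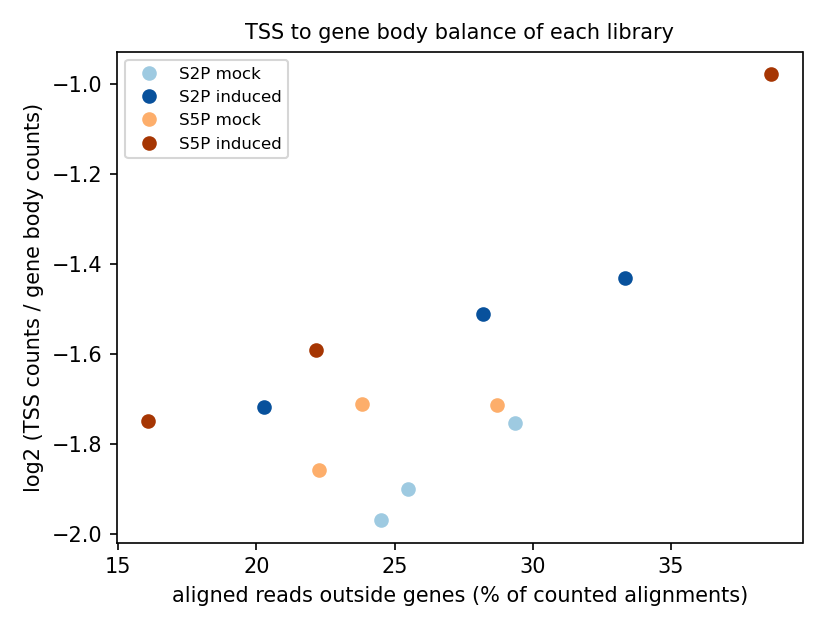
log2 of TSS counts over gene body counts of each library, against the share of its counted alignments that fall outside genes, for the 12 libraries in 4 groups. S5P induced replicate 2 lies farthest to the right, at 38.6% and -0.98.

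S5P and S2P occupancy were compared in mock plants. With the replicate number as a block, AT3G60935 was higher in S5P, at 8.91 ± 10.7 CPM for S2P and 82.3 ± 82.2 CPM for S5P (SD, n = 3). EARLI1 (AT4G12480), a lipid transfer protein gene, was higher too, at 57.9 ± 23.4 and 111 ± 36.9 CPM, and AT5G33330 lower, at 180 ± 105 and 61.3 ± 34.0 CPM (SD, n = 3). In that paired fit their log2 differences were 4.52 (SE 0.31), 1.08 (SE 0.21) and -1.60 (SE 0.20), with adjusted p of 3.39e-45, 0.000284 and 1.68e-11 in edgeR, each the lowest over its alternative settings, where the highest was 1. Without the block the log2 differences were 3.69, 0.92 and -1.56, and over the settings they ran from 2.21 to 4.52, 0.58 to 1.16 and -1.99 to -1.01. The replicate block gave 230 genes, 98 higher and 132 lower in S5P. In each pair the S5P library had the lower share of reads outside genes (23.8% against 25.5%, 28.7% against 29.4% and 22.3% against 24.5%). The paired fit therefore cannot tell the antibody apart from that share. Without it edgeR called 0 of 16388 genes, with 372 at an unadjusted p under 0.05, and DESeq2 and limma voom called 0.

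Among the lists, photosynthesis, histones, touch, cold and elicitor early response, DNA damage, glucosinolates and circadian clock genes were higher in S5P of mock plants, with medians from 0.18 for the clock to 0.51 for touch and cold, where 22 of 23 were positive. Camera's adjusted p ran from 0.00437 to 0.0482, and with an estimated correlation none passed, with adjusted p from 0.664 to 0.772. The list differences, too, cannot be told apart from the lower share of reads outside genes in the S5P mock libraries. With that share as a covariate camera called fewer lists. The share of reads in the TSS window was 21.5% for S2P and 22.8% for S5P, a log2 difference of 0.11 (exact two-sided permutation p = 0.2, unpaired). In each same-numbered pair log2 TSS over gene body was higher for S5P (-1.71 against -1.90, -1.71 against -1.75 and -1.86 against -1.97). As a median over genes, with 1 count added to each window, the difference was -0.14. The added count pulls shallow libraries toward 0. Single genes' TSS to gene body ratios gave 0 calls of 1527 in edgeR, with 37 at an unadjusted p under 0.05, 0 by limma and 5 with the replicate block.

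Whether the response to induction differed between the antibodies was tested as an interaction. The log2 difference between the responses was 0.42 (SE 0.65) for TFIIS and -0.11 (SE 0.65) for AT2G04070. In edgeR 0 of 23793 genes passed, with 151 at an unadjusted p under 0.05; DESeq2 and limma voom called 0 genes, and camera 0 lists. In simulated data this test recovered 50% of genes whose response differed 8-fold and 13.4% of those that differed 4-fold, so smaller differences were mostly not detectable. Since the labels pair each antibody with another form of the induced protein, the term holds both differences.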

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

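Settings with the fit over both antibodies, deep libraries, summed antibodies, the share of reads outside genes, and the list tests with libraries left out or blocked were added after the data had been seen. Where a cause is not given by fewer genes or samples, the cause was not tested. S2P whole gene calls (3) were 0 with RLE, upper quartile, cyclic loess and organelle genes kept in, 14 with total counts, 42 with DESeq2, 1 with voom, 72 without a filter, 78 in deep libraries (1 mock library, assumed to vary like the 2 induced) and 204 with the share outside genes; leaving out a library gave 0 to 526. S2P gene body calls (1) were 0 with RLE and upper quartile, 7 with total counts, 24 with DESeq2, 68 without a filter, 5 with a minimum count of 30 and 186 with the share outside genes, and 0 to 340 with a library left out. S2P TSS window calls (0) were 38 with cyclic loess, 3 with the share outside genes and up to 3 without S2P induced 3, and S2P ratio calls (0) up to 2 without S2P induced 2. S5P whole gene calls (0) were 92 with DESeq2, 28 without a filter, 302 in deep libraries, which is the fit without S5P induced 2, 768 with the share outside genes and 0 to 302 with a library left out. S5P gene body calls (0) were 52 with DESeq2, 49 without a filter, 514 with the share outside genes and 0 to 148 with a library left out; S5P TSS window calls (0) were 160 with the share outside genes and up to 11 without S5P induced 2. Antibody calls in mock plants (0) were 2 without a filter. Calls over both antibodies (491) were 1874 with DESeq2, 297 with voom, 270 with cyclic loess, 767 in deep libraries, 977 with summed antibodies, 2942 with the share outside genes and 199 to 970 with a library left out.

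Correlations of deviations of same-numbered mock and induced libraries were 0.131, -0.164 and -0.326 for S2P and -0.005, 0.283 and 0.424 for S5P, not above 0.1 for every number of either antibody, so the numbers were not taken to pair them. With the replicate block, S2P whole gene and gene body calls were 0, S5P gene body calls 2 and calls over both antibodies 281; antibody calls in mock plants were 230 and ratio calls 5. The paired list tests with an estimated correlation called 0 lists, and the block changed no other call.

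List calls were 0 with an estimated correlation for S2P (6), S5P (5) and the antibodies (6), and 2, 0 and 0 with fry. S2P lists were 11 with cyclic loess, 12 in deep libraries and 5 to 10 with a library left out, the highest without S2P induced 3; S5P lists were 8 in deep libraries and 4 to 8 with a library left out; antibody lists were 2 with the share outside genes and 1 to 7 with a library left out. The log2 fold change of TFIIS in S5P passed in deep libraries, the fit without S5P induced 2 (1.82, against a lowest of 1.25 with a library left out) and with the share outside genes (1.41), with adjusted p from 0.00649 to 0.989 over 18 settings. The TSS balance of S2P was -0.050 as a median over genes and 0.57 over genes past the filter in both windows, and that of the antibodies -0.14 as a median over genes; with a library left out or in deep libraries it kept its sign. The median log2 fold change of all genes, 0.035 for S2P, -0.0083 for S5P and -0.0023 over both antibodies, was -0.16, -0.15 and -0.18 with total counts and -0.09, -0.16 and -0.13 with upper quartile factors. Values of single named genes kept their direction and side of the threshold in 2819 cases, newly passed in 276 and reversed in 0. In 261 cases they no longer passed or were given no adjusted p, and the latter include genes that had not passed in the main fit. Shallow libraries limit S2P mock to 1 deep library.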

Other observations

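The fit over both antibodies, the gene families, the alternative respiration list, the share of reads outside genes as a covariate and every test below except cyclic loess and silent genes for the S2P calls, and the regroupings for whole gene calls within each antibody, were chosen after the results had been seen.

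In a fit of induction over both antibodies, 415 of 23793 genes rose and 76 fell. Of these 491, 188 had no overlap between mock and induced libraries within either antibody, 137 higher and 51 lower. The rising and falling genes named next, apart from TFIIS, were picked from those 188 by fold change. SRO2 (AT1G23550), a relative of SRO3, had a log2 fold change of 3.44 (SE 0.49), AT5G52760 3.38 (SE 0.56), the glutathione transferase gene GSTU11 (AT1G69930) 3.10 (SE 0.59) and NAC13 2.88 (SE 0.33), with edgeR adjusted p of 0.000812, 0.00248, 0.00646 and 0.00022; over 25 other settings GSTU11 lost its call in 1, with adjusted p up to 0.0703, and the others in 0. Genes that fell included the transcription factor gene RRTF1 (AT4G34410) with -2.07 (SE 0.45), the dehydrin genes ERD10 (AT1G20450) and COR47 (AT1G20440) with -1.73 (SE 0.34) and -1.66 (SE 0.41), the galactosidase gene BGAL1 (AT3G13750) with -1.69 (SE 0.42) and the cell wall gene XTH4 (AT2G06850) with -1.44 (SE 0.35). Their adjusted p in edgeR were 0.0165, 0.00785, 0.0394, 0.0389 and 0.0365, and over 25 other settings, 24 for RRTF1, the calls were lost in 6, 1, 9, 11 and 12, with adjusted p up to 0.154, 0.0640, 0.195, 0.125 and 0.152. TFIIS rose by 1.36 (SE 0.31, adjusted p = 0.0259 in edgeR; from 2.91e-05 to 0.101 over 25 other settings). Same-numbered libraries of the antibodies deviated together in mock plants (0.223, 0.309 and 0.495) and oppositely in induced plants (-0.308, -0.701 and -0.541), so they are not independent, which this fit assumes. Induced libraries of different numbers were related too. S2P induced 1 had 0.404 and -0.418 with S5P induced 2 and 3. S2P induced 2 had 0.446 and 0.779 with S5P induced 1 and 3. S2P induced 3 had -0.271 and 0.471 with S5P induced 1 and 2. Sums or splits by number do not account for these relations. With counts summed over the antibodies 977 genes passed. Opposite deviations of the induced libraries partly cancel in these sums, which can lower the spread and raise that count. With the replicate block 281 genes passed, with voom 297 and with cyclic loess 270. With total counts the calls were 242 higher and 129 lower, and with upper quartile factors 296 and 136. Leaving out S2P mock 3 gave 199 calls, S5P mock 3 225, S2P induced 1 248, S5P induced 1 262, S5P mock 1 287, S5P mock 2 314 and S5P induced 2 970. Of the 19 lists, the 6 called higher for S2P were higher and photosynthesis lower; with an estimated correlation salicylate and defence alone passed, with adjusted p = 0.00279.

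Genes of alternative respiration carry electrons past the proton-pumping complexes of mitochondria. Of 12 such genes, written down after some had been seen among the calls of the same fit, so that a test of the list there is void, 4 passed over all genes and 10 were positive, with a median log2 fold change of 0.48. NDB4 (AT2G20800) had 2.90 (SE 0.40), AOX1D (AT1G32350) 2.63 (SE 0.33), AOX1A (AT3G22370) 1.63 (SE 0.36) and NDB2 (AT4G05020) 1.22 (SE 0.31); over 25 other settings AOX1A lost its call in 10 and NDB2 in 16, and NDB4 and AOX1D in 0. Of 218 families defined by the start of their symbols, 12 passed camera with the preset correlation and 0 with an estimated one. NRPB genes, subunits of RNA polymerase II, had a median of 0.65 with 14 of 15 positive and 3 past the threshold, NRPB6A (AT5G51940) with 1.34 (SE 0.26), NRPB12 (AT5G41010) with 1.25 (SE 0.30) and NRPB8A (AT1G54250) with 1.14 (SE 0.25); adjusted p = 0.264 with an estimated correlation. Over other settings NRPB6A lost its call in 1 of 25, NRPB12 in 15 of 25 and NRPB8A in 6 of 24. PTAC genes, of the plastid transcription machinery, had -0.47 with 1 of 13 positive and adjusted p = 0.519 with an estimated correlation. The medians of these 3 sets kept their sign in 7 of 7 scalings for each antibody.

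Unequal enrichment between libraries could account for the S2P calls, and the tests set for it before the data were examined did not decide. Of the 3 calls, 0 passed with voom and cyclic loess, but voom alone had already ended those of UGT74E2 and SRO3 (adjusted p = 0.0600 each in limma), so cyclic loess ended that of AT2G04070 (0.0355 with voom). The log2 fold changes hardly moved: AT2G04070 had 3.10 (SE 0.32) with voom and cyclic loess against 3.26 (SE 0.33) with voom alone, UGT74E2 2.71 (SE 0.32) against 2.72 (SE 0.34) and SRO3 2.88 (SE 0.39) against 2.95 (SE 0.36), and adjusted p went to 0.0541, 0.0680 and 0.131 (over 18 settings from 5.37e-06 to 0.422, 0.000251 to 0.499 and 0.000548 to 0.499). Silent genes lay 0.01 from the median of all genes, with a bootstrap SE of 0.40 over 10 genes, too wide for the bound of 0.1 set in advance. The share of reads outside genes is argued against as the whole cause, since with it as a covariate, a setting picked later, all 3 passed among 204 calls (adjusted p = 0.000548 each in edgeR) with log2 fold changes of 3.23 (SE 0.37), 2.91 (SE 0.34) and 2.92 (SE 0.34), while enrichment that this share does not follow stays open.

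The higher share of reads near the TSS in induced libraries was weighed against reads outside genes and depth. In every library TSS and gene body counts together exceeded whole gene counts, though they cover fewer genes (S2P mock 1: 35243 and 131475 against 159951). The windows may thus overlap or reach outside genes. Some reads may then count both in the TSS window and as outside genes, so the relation of these 2 measures may be partly built in. Within groups, log2 TSS over gene body followed the share outside genes over the 12 libraries (Pearson r = 0.967, Spearman rho = 0.944, r = 0.905 without the 2 farthest libraries) and depth (r = -0.747, rho = -0.72, r = -0.697); with same-numbered libraries of the antibodies permuted together, exact permutation p was 0.0278, the smallest possible, and 0.0556 for both coefficients, and 0.0556 adjusted over the 2 relations for each. The difference of 0.32 over both antibodies was 0.298 with that share in the regression (SE 0.03) and 0.356 with depth (SE 0.09), so neither alone accounts for it; with same-numbered libraries kept together exact permutation p was 0.1 for each, the smallest that 20 relabellings allow. As a median over genes, with 1 count added to each window, the S2P difference was -0.050. The added count pulls ratios toward 0 where reads are few. S2P mock 1 and 2 had medians of 3 and 4 reads per gene, so this median cannot show which genes carry the difference. Without S5P induced 2 the S5P difference was 0.09, so unadjusted it may rest on few libraries. Adjusted for the share outside genes, induced libraries lay above all mock libraries (S5P from -1.47 against up to -1.64, S2P from -1.66 against up to -1.86). Tests of single genes scaled each window on its own, which removes a shift shared by all genes. They therefore cannot show whether single genes shared the higher TSS share. At an unadjusted p under 0.05 in edgeR, 17 S2P ratios were higher and 13 lower, with a median of 0.04 over all genes. For S5P 15 were higher and 62 lower, with a median of -0.08. Over both antibodies 73 genes passed higher and 104 lower in the TSS window, against 342 and 117 in the gene body. Induction as the source was not tested apart from the groups.

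The induced libraries of replicate 2 stood apart from their groups. Dividing the 6 induced libraries into S2P induced 1 and 3 with S5P induced 2, against S2P induced 2 with S5P induced 1 and 3, called 2674 genes, and the antibodies themselves 0. The mean difference between 96 genes higher and 132 lower in S5P of mock plants (those of the paired fit without AT3G60930 and AT3G60935) followed the share of reads outside genes over the 6 induced libraries (Spearman rho = -1, exact permutation p = 0.00278, the smallest possible; Pearson r = -0.988, exact permutation p = 0.00139; r = -0.964 without the 2 farthest), consistent with a difference in background. Exchanged antibody labels could give the same division and stay open: at AT3G60930 and AT3G60935, the library labelled S5P induced 2 had 164 CPM (95% counting interval 98.7 to 256, from 19 counts) and that labelled S2P induced 2 had 14.7 CPM from 17 counts, the levels of their own antibodies, but these neighbours are 1 locus chosen after its values were seen, and S2P mock 2, at 41.7 CPM, lay above S5P induced 1, at 36.4 CPM.

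Other divisions of the same libraries were counted beside each result. With 10 divisions of 6 libraries, or 4 within replicate numbers, a share under 0.05 cannot be reached. For S2P, 3 of the 10 gave as many whole gene calls as the real 3, and the highest other gave 564, which set S2P mock 1 with S2P induced 1 and 3 and points to structure in the libraries other than induction. S2P gene bodies gave 3 of 10 (real 1, highest other 437), the TSS window and the ratio 10 of 10 each (real 0, highest others 49 and 390), and gene lists 4 of 10 (real 6, highest other 8). For S5P, the whole gene, TSS window, gene body and ratio gave 10 of 10 each (real 0, highest others 0, 1, 0 and 1) and gene lists 6 of 10 (real 5, highest other 9). With the share outside genes as a covariate the real division gave the most calls for both antibodies, 1 of 10 each (real 204 and 768, highest others 28 and 5). Antibodies in mock plants gave 10 of 10 for whole genes and ratios (real 0, highest others 1 and 59), 1 of 4 in the paired fit (real 230, highest other 2), and 10 of 10 in induced plants (real 0, highest other 2674).

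Over both antibodies, same-numbered libraries were kept together, since mock libraries pair by number, which leaves 10 splits and no share under 0.05; the numbers do not pair the induced libraries, whose opposite deviations partly cancel there. The real split gave the most calls, 1 of 10 each (real 491, highest other 0; with the share outside genes real 2942, highest other 156). Among 60 regroupings that broke the pairs, the highest others were 156 and 1786, and the interaction's 0 calls were reached by 60 of 60, with up to 111. The correlation of log2 differences between the antibodies over 23793 genes was 0.463, which 6 of 100 pairs of divisions reached, up to 0.557, so chance is not excluded there; genes are not independent replicates.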
